A study of Mus musculus with 24 samples.

How the data were processed

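Parietal cortex of C57BL/6 mice was profiled in 24 libraries, 6 animals in each of 4 groups. Mice aged 3 or 18 months either had a permanent occlusion of the middle cerebral artery (MCAO), a surgical model of ischaemic stroke in which the vessel is coagulated and severed, with tissue taken 3 days later, or were left intact as controls. The controls were not operated, so each comparison of MCAO with control also holds the effects of anaesthesia and surgery. Per the labels' protocols, total RNA was treated to remove DNA and 400 ng entered a QuantSeq library preparation, which primes at the poly(A) tail and reads the 3′ end of each transcript. Library letters A to F name the animals within a group, and the labels do not say that they pair animals between groups.

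The authors deposited 2 tables for each library. The first holds counts of reads per gene, which the submitters' processing notes tie to Trimmomatic for trimming, HTSeq for counting and the mouse genome build GRCm38, without versions; the aligner and the gene annotation are not given in the sources used here. It lists 46983 gene identifiers, 92 spike-in transcripts of the External RNA Controls Consortium (ERCC) and 5 summary lines of the counting program. The second deposited table holds a signal that proved to be the same counts divided by 1 size factor per library, with a relative spread of at most 9.5e-07, and DESeq2 is named in the submitters' processing notes. The counts were used for every test, and the normalised signal only for that check.

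Of the gene identifiers, 46488 were matched to a symbol through the supplied table of gene names. Coordinates are from the GENCODE M21 annotation of GRCm38. Spike-ins and summary lines stayed out of library sizes and tests. Reads outside any gene made up 25.7% to 34.5%, and ambiguous reads 0.464% to 0.581%, of a library's total. That total holds reads on genes, on spike-ins, outside any gene and ambiguous ones. Alignments that were not unique, 2665289 to 10180255 per library, stayed out of it and of the gene counts. Spike-ins took 4.43% to 10.5% of counts on genes and spike-ins together.

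Gene counts per library ran from 3.30 to 13.1 M with a median of 5.15 M. All 60 pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 3.38 to 76.1, so no library was treated as a copy of another. Intervals and floors on low counts cover counting error only, since the reads carry no molecular identifiers.

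Differential expression was tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. All 24 libraries entered 1 model with 4 group means, TMM scaling, the default filter on low counts (a minimum of 10 counts), robust dispersion estimates and the quasi-likelihood F test, two-sided. The filter kept 14599 genes and left 32384 untested. The biological coefficient of variation was 0.207. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and the error given with a log2 fold change (±) is its standard error. The 5 comparisons were MCAO against control at each age, 18 against 3 months in control cortex and after MCAO, and the difference of the MCAO effect between the ages (an interaction term).

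Before the data were examined, 44 gene lists were fixed, covering cell types of the cortex, blood and neighbouring tissue, and pathways of injury, immunity and neuronal function. Lists with at least 5 tested members, 39 in all, were tested with camera on the same model, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, Benjamini-Hochberg adjusted over the lists. Unless another setting is named, the adjusted p of a list is the one with an estimated correlation. For each list the number of members past the threshold is given as adjusted over all genes and as adjusted over the list alone. A library's list score is the mean log2 counts per M (CPM, M standing for mega, prior count 2) over tested members.

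Genes were named by a rule fixed beforehand: among genes past the threshold with a mean of at least 5 CPM in a compared group and no overlap between the groups, the 10 with the largest log2 change in each direction, leaving out predicted genes and pseudogenes, with the overlap condition dropped for the interaction. To these were added, of each list described, the first 3 members and the 3 with the smallest p, and sex-linked genes. A gene named for 1 comparison may be given in the others, and a few genes that the rule names are not reported here. Where a group held no count of a gene, the fold, taken on the pooled counts of each group, is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of CPM is given with its 95% interval.

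Library measures were compared by exact permutation tests and relations between list scores by Pearson and Spearman correlations with permutation p-values. The tests were tried on simulated counts with 200 changed genes per comparison. Recovery of changes of 1.5-fold, 2-fold and 4-fold was 37.3%, 80.6% and 96.8% for MCAO at 3 months, 47.0%, 81.8% and 98.5% for MCAO at 18 months, 29.9%, 83.6% and 97.0% for age in controls, and 37.3%, 67.7% and 100% for age after MCAO. For the interaction it was 14.9%, 46.3% and 89.1%. Of the simulated calls, 3.85%, 6.40%, 4.43%, 1.36% and 3.85% were false in these 5 comparisons. Apart from the changed genes, all simulated groups shared the same mean and dispersion of each gene. Differences in rate between the comparisons of group pairs are therefore mainly those of the random draw. The rates do not hold for the real MCAO comparisons, where far more genes changed and libraries within a group were less even.

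Alternatives fixed beforehand were other scalings (median-of-ratios, library totals, upper quartile), other filters, DESeq2 1.42.0, limma voom with sample weights, a fit of the compared groups alone, the letter as a block, thinning of all libraries to 3.30 M counts, each library left out in turn and a neuron marker score as a covariate. Chosen after the data were seen were the letters A to C or D to F alone or as a block, scaling by spike-ins and a correction for GC content of the last 200 bases of the longest transcript. Fits without 3 sets of libraries, described in the Results, were also chosen then. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.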

Results

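The study measured gene expression in parietal cortex of young (3 months) and aged (18 months) C57BL/6 mice 3 days after permanent MCAO and in intact mice of the same ages, with 6 animals per group. The question is how the response of the cortex to focal ischaemia differs between young and aged animals. Gene counts averaged 5.18 ± 1.38 M per library in controls of 3 months and 4.87 ± 1.00 M in controls of 18 months. They averaged 6.08 ± 3.45 M after MCAO at 3 months and 6.05 ± 1.80 M after MCAO at 18 months (mean ± SD, n = 6). The first principal component, taken over the most variable genes alone, carried 72.7% of their variance. Spike-in RNA took 9.10 ± 1.04% of counts after MCAO at 3 months against 6.36 ± 1.21% in controls (exact permutation p = 0.00433, adjusted 0.0519 over 24 tests). At 18 months it took 8.14 ± 1.43% against 6.29 ± 1.27% (exact permutation p = 0.0411, adjusted 0.165). All folds below are relative to the TMM scaling of the genes themselves. Xist, the noncoding RNA of the inactive X chromosome, was expressed in every library, from 467 CPM upward.

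A few libraries stood apart within their groups. Libraries A and C of MCAO at 3 months differed from the other 4. Choroid plexus transcripts were high in library D of the young controls (score 5.62, others at most 1.78) and in library C of MCAO at 3 months (score 6.09, others at most 2.78). The score of erythrocytes was 6.16, 4.33 and 7.84 in libraries C, E and F of MCAO at 18 months, where the group mean was 4.46 ± 2.18. The group mean after MCAO at 3 months was 2.52 ± 1.08. Library E thus lay near its own group mean, and none of these 3 scores was flagged as far from its group.

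At 3 months, MCAO raised genes of phagocytes, reactive astrocytes, dividing cells and the extracellular matrix and lowered genes of neurons. Gfap, the intermediate filament of astrocytes (ENSMUSG00000020932, GRCm38 chromosome 11, 102887336 to 102900912), rose 22.3-fold from 11.2 ± 0.725 to 249 ± 35.2 CPM (log2 fold change 4.48 ± 0.16, adjusted p = 3.9e-17). Spp1, encoding osteopontin (chromosome 5, 104435118 to 104441050), rose from 2.40 ± 0.77 to 317 ± 118 CPM, and Lgals3, encoding galectin-3 of activated phagocytes, from 0.256 ± 0.336 to 58.4 ± 31.4 CPM (adjusted p = 4.8e-11). Neurod6, a transcription factor of excitatory cortical neurons (chromosome 6, 55677822 to 55681263), fell from 167 ± 23.8 to 65.2 ± 24.3 CPM (log2 fold change -1.36 ± 0.20).

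Of 14599 genes tested, 5451 changed, 2930 up and 2521 down. Of these, 1661 rose and 140 fell by at least 1 on the log2 scale. Of all 14599 tested, the 2 groups did not overlap in 2752, where chance gives 0.216%, and 2716 of these were among the changed genes. Several of the most strongly raised genes had no count in any of the 6 control libraries. Cd5l, encoding a secreted macrophage protein, reached 84.8 ± 99.4 CPM. On the pooled counts of each group, in which library A weighed most, it was at least 1225-fold higher than in controls. Its fitted log2 change was 11.9, and 10.9 without library A of MCAO. It had 279 CPM in library A and 5.51 to 80.3 CPM in the others. H19, an imprinted noncoding RNA, was at least 214-fold higher and Mmp3, a matrix metalloproteinase, at least 97.6-fold. Tgm1, a transglutaminase, was at least 81.4-fold higher, Lrrc15 at least 70.6-fold and Lcn2, encoding lipocalin-2, at least 46.7-fold. Cd300lf was 378-fold higher (95% counting interval 129 to 1835) and Arg1, arginase-1 of infiltrating macrophages, 265-fold (73.2 to 2195). Msr1, a scavenger receptor, rose by 7.51 ± 0.61 on the log2 scale. The largest falls were smaller. They were led by Cyp4f15 (-1.58 ± 0.25), BC030500 (-1.48 ± 0.33), the homeobox gene Mkx (-1.43 ± 0.25), Adcyap1, which encodes the neuropeptide PACAP (-1.42 ± 0.23), and the Wnt agonist Rspo1 (-1.41 ± 0.24). Next came Ovol2 (-1.37 ± 0.22), the receptor kinase Ltk (-1.36 ± 0.19), Wnt9a (-1.35 ± 0.22) and AI593442 (-1.34 ± 0.21).

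**Figure D1:**
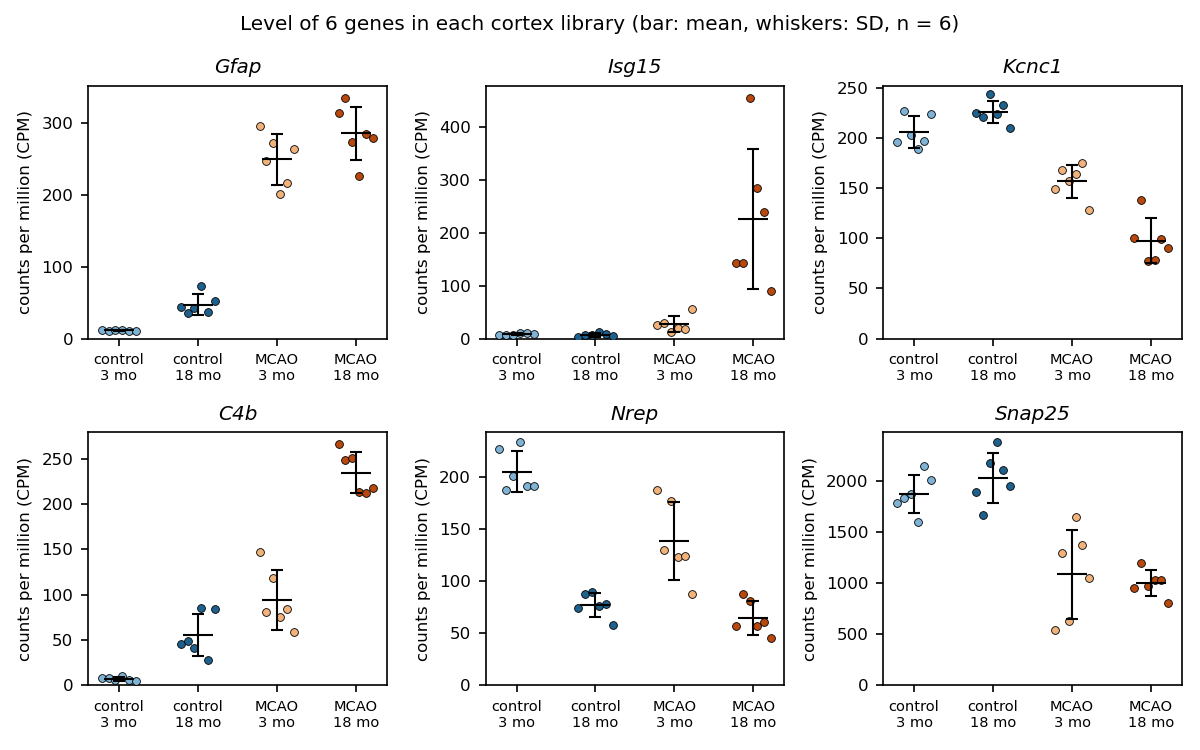
CPM of 6 genes (vertical axes) in each of the 24 libraries (points), by group on the horizontal axis, with the group mean (bar) and SD (whiskers), n = 6 animals. Gfap stood at 10.4 to 12.0 CPM in young controls and at 35.5 to 73.3 CPM in aged controls, and Isg15 was highest after MCAO at 18 months, from 90.8 to 456 CPM.

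Among cell types, all 12 resident microglia markers rose at 3 months (median log2 change 1.60, adjusted p = 0.002, 12 adjusted over the list alone), with Cx3cr1 at 1.86 ± 0.24, Tmem119 at 1.63 ± 0.27 and P2ry12 at 0.69 ± 0.20. All 11 markers of monocytes and infiltrating macrophages rose (median 4.46, 3.66 with genes absent from controls at their bound, adjusted p = 0.008), among them the chemokine receptor Ccr2 (5.26 ± 0.68, and 4.41 without library F of MCAO) and fibronectin Fn1 (3.20 ± 0.29). So did all 7 neutrophil markers (median 5.57, at the bound 5.02, adjusted p = 0.0077). Of 18 neuronal markers 15 fell (16 adjusted over the list alone, median -0.56, adjusted p = 0.011). They included Rbfox3, the nuclear antigen NeuN (-0.56 ± 0.12), Syt1, the calcium sensor of transmitter release (-0.93 ± 0.17), and Snap25 of the vesicle fusion machinery, at 1087 ± 436 against 1875 ± 189 CPM (-0.79 ± 0.18). Without libraries A and C, where it was lowest, the log2 change of Snap25 was -0.49, and that of Cx3cr1 1.19. Interneuron markers fell in 6 of 12 cases (6 adjusted over the list alone, adjusted p = 0.052). Of 12 general astrocyte markers, 4 rose and 2 fell (median 0.00, and -0.47 with spike-in scaling, adjusted p = 0.87), whereas 8 of 12 endothelial markers rose (8 over the list alone, median 0.79, adjusted p = 0.025). In this and the other comparisons, each list with an adjusted p under 0.05 with an estimated correlation had a median of the same sign when libraries were scaled by totals or by spike-ins.

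Pathway lists moved in the same comparison. All 18 reactive astrocyte genes rose (median 3.95, adjusted p = 6.3e-05), with the filament Vim at 4.21 ± 0.24 and the protease inhibitor Serpina3n at 4.05 ± 0.23. All 25 cell cycle genes rose (median 3.39, adjusted p = 1.7e-05), including the proliferation marker Mki67 (6.59 ± 0.46), the topoisomerase Top2a (6.45 ± 0.34) and cyclin Ccnb1 (1.54 ± 0.27). All 24 genes of extracellular matrix and scar rose too (median 3.28, adjusted p = 0.011). Markers of fibroblasts and meninges rose in 7 of 10 cases (median 2.81, adjusted p = 0.098 with an estimated correlation) and those of pericytes in 8 of 10 (median 0.77, adjusted p = 0.052 with an estimated correlation). Genes associated with phagocytic microglia rose in 20 of 21 cases (median 3.08, adjusted p = 0.002). Trem2, a lipid receptor of microglia, rose by 3.26 ± 0.31, and the exception was Apoe (0.23 ± 0.15, adjusted p = 0.25). Of 19 chemokines and cytokines 17 rose (18 adjusted over the list alone, median 4.05, adjusted p = 0.0024), with Ccl2 at 6.46 ± 0.79, Il1b at 1.79 ± 0.46 and Ccl3 176-fold higher (31.2 to 6966). Of 13 complement genes 11 rose (median 2.76, adjusted p = 0.0023), with C4b at 3.81 ± 0.27. MHC class I genes, which present antigen (MHC, major histocompatibility complex), rose in 10 of 11 cases (median 1.54, adjusted p = 0.026) and all 7 class II genes rose (median 3.72, adjusted p = 0.037). Interferon response genes rose in 26 of 32 cases (29 up and 1 down adjusted over the list alone, median 1.84), with adjusted p = 0.064 with an estimated correlation. Ifit1 was at 1.63 ± 0.46, Ifit3 at 1.47 ± 0.28 and Isg15, a ubiquitin-like protein induced by interferon, at 1.74 ± 0.40. Glutamatergic synapse genes fell in 14 of 19 cases (16 over the list alone, median -0.52, adjusted p = 0.008), including Grin1 (-0.52 ± 0.15), Gria1 (-0.49 ± 0.10) and Dlg4 (-0.40 ± 0.13). Presynaptic genes fell in 16 of 19 cases and ion channel genes in 12 of 18, each with adjusted p = 0.064 with an estimated correlation. In the same comparison the haemoglobin genes Hba-a1 (2.82 ± 1.39, adjusted p = 0.12) and Hbb-bs (3.27 ± 1.12, adjusted p = 0.027) were higher by similar sizes, and only the second passed the threshold, which it lost in 2 of the 24 fits with 1 library left out.

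At 18 months, MCAO raised genes of phagocytes, reactive astrocytes, dividing cells, the interferon response and antigen presentation and lowered genes of neurons. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484) had no count in the 6 control libraries and 45.3 ± 19.2 CPM after MCAO, at least 432-fold higher. Isg15 (chromosome 4, 156199424 to 156200818) rose 32.8-fold from 6.78 ± 3.37 to 226 ± 133 CPM (adjusted p = 1.7e-09). Ube2c, which drives exit from mitosis, rose from 0.156 ± 0.208 to 40.6 ± 10.4 CPM, and Syt2, a synaptotagmin of fast inhibitory terminals, fell from 82.5 ± 11 to 22.7 ± 12.1 CPM (log2 fold change -1.86 ± 0.22).

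At this age 6606 genes changed, 3463 up and 3143 down. Of these, 1971 rose and 285 fell by at least 1 on the log2 scale. The groups did not overlap in 3938 of all 14599 genes tested (chance 0.216%), and 3862 of these were among the changed genes. Absent from all control libraries were Lrrc15 (at least 76.0-fold higher after MCAO), Cd300ld (at least 71.0-fold), Tfpi2 (at least 68.0-fold) and Selp, encoding P-selectin (at least 62.8-fold). Cd5l was 850-fold higher (152 to 33590), Apoc2 288-fold (51.4 to 11410) and Mmp3 220-fold (60.6 to 1818). Pclaf, a factor of DNA replication, rose by 7.76 ± 0.50 on the log2 scale. Falls were led by Iqcj (-2.09 ± 0.29), Tcap (-2.07 ± 0.28), Cbln4, a synaptic organiser (-2.05 ± 0.40), Pld5 (-1.92 ± 0.26). Also low were the potassium channel subunits Kcns1 (-1.89 ± 0.27) and Kcnab3 (-1.77 ± 0.28), Rspo1 (-1.81 ± 0.24), Barx2 (-1.78 ± 0.36) and Ddit4l (-1.72 ± 0.25).

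All 32 interferon response genes rose at 18 months (median 3.75, adjusted p = 0.0077), with Ifit1 at 3.98 ± 0.38 and Ifit3 at 3.12 ± 0.26. All 11 genes of antigen presentation by MHC class I rose as well (median 3.05, adjusted p = 0.0069). The light chain B2m rose by 2.41 ± 0.16, H2-K1 by 3.05 ± 0.22 and H2-D1 by 2.45 ± 0.17. All 18 reactive astrocyte genes (median 3.49, adjusted p = 0.00017) and all 25 cell cycle genes (median 3.81, adjusted p = 0.00017) rose. So did all 21 phagocyte genes (median 2.55, adjusted p = 0.0042), all 12 microglia markers (median 1.40, adjusted p = 0.0042) and all 11 monocyte and macrophage markers (median 4.50, adjusted p = 0.0049). Gfap rose by 2.59 ± 0.14, from a control level of 47.3 ± 14.1 CPM, Vim by 4.69 ± 0.24 and Serpina3n by 3.60 ± 0.20. Endothelial markers rose in 10 of 12 cases (median 1.41, adjusted p = 0.0042), with the adhesion molecules Cdh5 at 2.94 ± 0.23 and Pecam1 at 2.50 ± 0.27, the junction protein Cldn5 at 2.07 ± 0.24 and the receptor Flt1 at 0.68 ± 0.13.

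Neuronal markers fell in 16 of 18 cases at 18 months (17 adjusted over the list alone, median -0.71, adjusted p = 0.0049), with Snap25 at -1.03 ± 0.19, Syt1 at -0.99 ± 0.17 and Rbfox3 at -0.95 ± 0.12. Ion channel genes fell in 16 of 18 cases (17 over the list alone, median -0.85, adjusted p = 0.0071). Among them were the sodium channel Scn1a (-1.43 ± 0.15) and the potassium channels Kcnc1 (-1.21 ± 0.11) and Kcna1 (-0.85 ± 0.20), while Scn2a did not pass (-0.33 ± 0.15, adjusted p = 0.07). Presynaptic genes fell in 18 of 19 cases (median -0.76, adjusted p = 0.0096), glutamatergic synapse genes in 16 of 19 (median -0.62, adjusted p = 0.0069) and interneuron markers in 7 of 12 (8 over the list alone, median -0.58, adjusted p = 0.02). The 4 tested haemoglobin and erythrocyte genes rose as well. Hba-a1 stood at 33.5 ± 52.6 CPM against 2.26 ± 2.00 CPM, with 137 CPM in library F alone, and its log2 change of 3.88 ± 0.93 was 2.51 without that library.

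**Figure D2:**
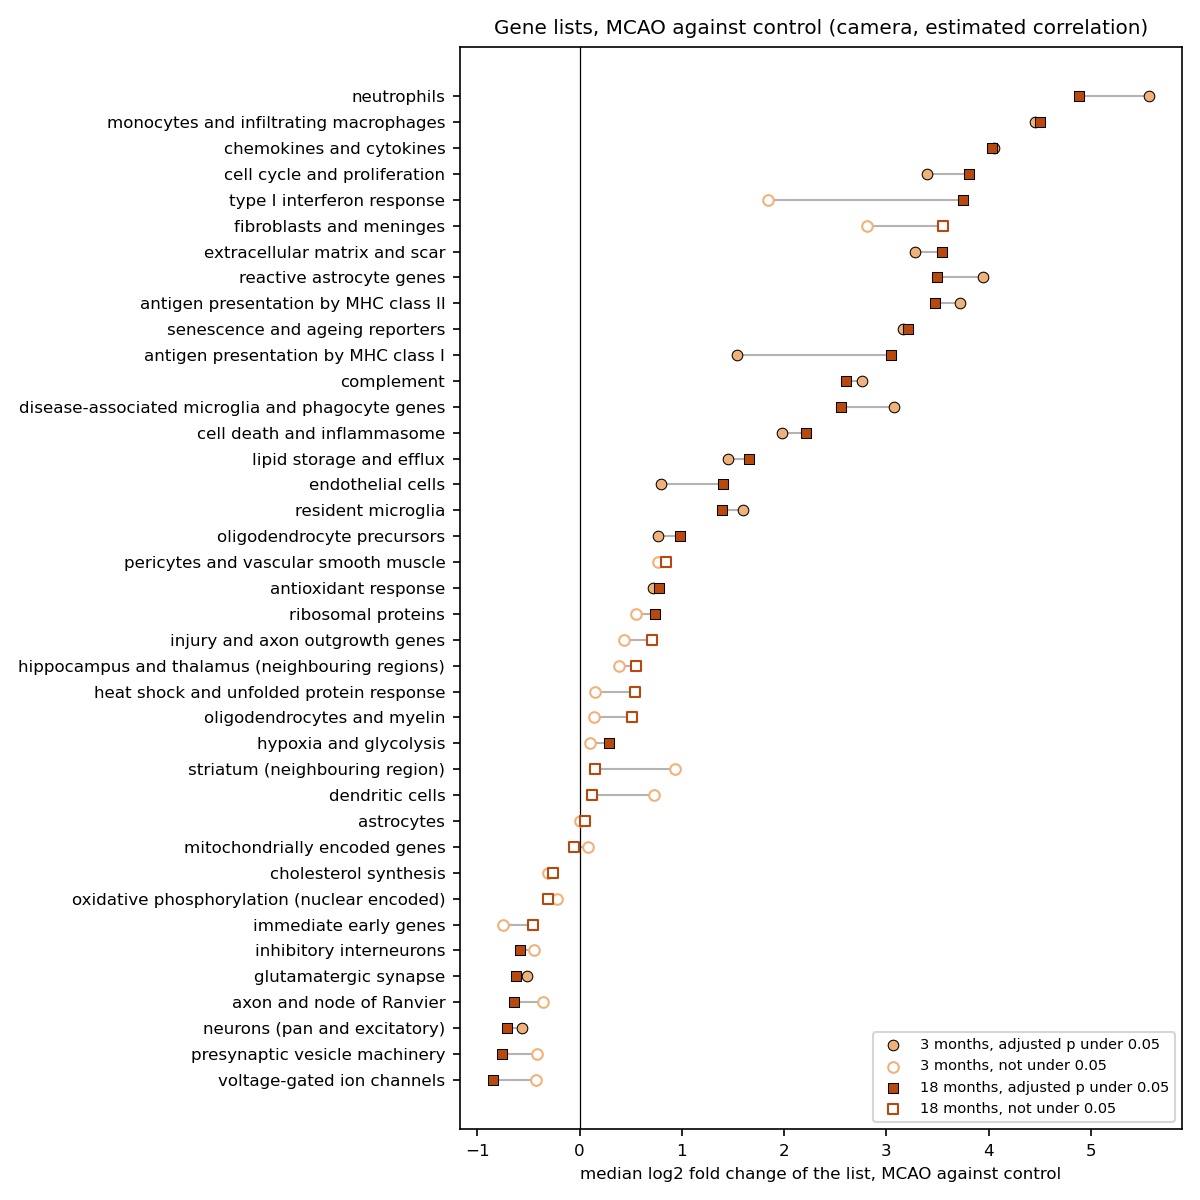
Median log2 fold change of MCAO against control (horizontal axis) for the 39 gene lists with at least 5 tested members (vertical axis), at 3 months (circles) and 18 months (squares), 6 libraries per group. Filled symbols mark lists with an adjusted p under 0.05 with an estimated correlation. The interferon list lay at 1.84 and 3.75, while the ion channel list lay at -0.42 and -0.85.

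Both ages shared most of the response. In the 2 comparisons, which have no library in common, 2546 genes rose at both ages and 1788 fell, 4334 in all, where independent lists would share 695 and 543. Only 6 genes changed in opposite directions. Across all genes the log2 changes correlated with r = 0.91, although genes are not independent replicates. Another 1111 genes passed the threshold at 3 months alone and 2266 at 18 months alone, but the difference of the effects was itself past the threshold in 4 of them, all among the latter.

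In control cortex, few genes differed between 18 and 3 months, and those that rose included genes of reactive glia. C4b, a complement component (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882), stood at 55.3 ± 23.7 CPM at 18 months against 6.64 ± 2.03 CPM at 3 months (log2 fold change 3.04 ± 0.27, adjusted p = 2.3e-07). Gfap stood at 47.3 ± 14.1 against 11.2 ± 0.725 CPM (2.08 ± 0.15, adjusted p = 2.7e-09). Nrep, a gene of neuronal growth and regeneration (chromosome 18, 33437019 to 33464029), fell from 206 ± 19.8 to 77.2 ± 11.4 CPM (-1.42 ± 0.16, adjusted p = 1.2e-05). Each of these held in 6 of 6 aged animals against all 6 young ones.

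In total 88 genes changed with age in controls, 51 up and 37 down, and 34 and 12 of them by at least 1 on the log2 scale. The groups did not overlap in 294 of all 14599 genes tested, where chance gives 0.216%, and 79 of these were among the changed genes. Cst7, a cystatin of activated microglia, rose by 5.06 ± 0.76, to 6.22 ± 5.53 CPM with 17.0 CPM in library D, and by 4.38 without that library. The receptor Clec7a (4.58 ± 0.61, and 3.98 without library D of the aged controls), the lipid droplet protein Plin4 (3.15 ± 0.48), the protocadherin Pcdhb8 (1.79 ± 0.35), Anln (1.67 ± 0.29) and the matrix linker Hapln2 (1.67 ± 0.23) rose too. Lyz2 (2.29 ± 0.51) and Spp1 (1.90 ± 0.44) passed the threshold but lost it in 9 and 17 of the 24 fits with 1 library left out. The receptor kinase Met fell by 2.14 on the log2 scale (SE 0.25). Smaller falls were those of Abi3bp (-1.67 ± 0.26), Klhl1 (-1.49 ± 0.29), Lypd1 (-1.02 ± 0.21), Susd5 (-1.01 ± 0.22), Marcksl1 (-0.99 ± 0.22), Prss12 (-0.93 ± 0.16), Aldh1b1 (-0.84 ± 0.15) and the transcription factor Sox4 (-0.82 ± 0.13). Marcksl1, Lypd1 and Susd5 lost their calls in 7, 3 and 2 of those fits. Xist was higher at 18 months, at 974 ± 206 against 541 ± 58.3 CPM (adjusted p = 0.0017), with 1391 CPM in library A.

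Of 4 lists called in aged controls, phagocyte genes rose in 5 of 21 cases (10 adjusted over the list alone, median 0.72, adjusted p = 0.015). Tyrobp was at 1.15 ± 0.26 (adjusted p = 0.029, lost in 7 of the 24 fits with 1 library left out), Trem2 at 1.22 ± 0.33 (adjusted p = 0.11) and Apoe at 0.28 ± 0.15 (adjusted p = 0.63). Chemokine and cytokine genes rose in 4 of 19 cases (7 over the list alone, median 0.94, adjusted p = 0.015). These were Ccl3, 29.3-fold higher (4.84 to 1197), Ccl4 (3.36 ± 0.52), Il33 (0.94 ± 0.15) and Spp1, which also stands in the phagocyte list. Ccl2 and Il1b were at 0.58 ± 1.63 and -0.12 ± 0.58. The complement list (13 genes, 7 over the list alone, median 0.78, adjusted p = 0.015) held 1 call over all genes, C4b, with C3 at 2.42 ± 0.85 (adjusted p = 0.29, and 1.29 without library D of the aged controls) and C1qa at 0.83 ± 0.32 (adjusted p = 0.38). The reactive astrocyte list held 2 raised genes, Gfap and Serpina3n (1.5 ± 0.26), with Vim at 0.66 ± 0.24 (adjusted p = 0.3), and 2 over the list alone (median 0.61, 0.58 with genes absent from a group at their bound, adjusted p = 0.033). Interferon response genes did not pass as a list (median 0.33, adjusted p = 0.48), with Ifit1 at 0.62 ± 0.52 and Ifit3 at 0.54 ± 0.30. The MHC class I list was not called either, but its median was 0.70 (scores of 3.43 ± 0.29 against 2.81 ± 0.25). Its member H2-D1 passed the threshold (0.70 ± 0.16, adjusted p = 0.042). Markers of blood cells were higher in the same comparison without a call as a list with an estimated correlation. Neutrophil markers had a median of 1.44 (1.06 with a gene absent from 1 group at its bound, 0 of 7 up, adjusted p = 0.18) and those of monocytes and infiltrating macrophages 0.60 (1 of 11 up, adjusted p = 0.29). The 4 erythrocyte genes, too few for a list test, had a median of 2.50 with 0 past the threshold (scores of 1.61 ± 1.27 against -0.04 ± 0.70). DESeq2 called 174 genes in this comparison and voom 426, and edgeR called 51 without library D of the aged controls and 137 without library A of MCAO at 3 months.

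After MCAO, the aged cortex had higher interferon response and MHC class I genes than the young cortex. The class I median was also positive with age in controls (0.70), though the list was not called there. Isg15 stood at 226 ± 133 CPM at 18 months against 26.9 ± 15.3 CPM at 3 months (8.39-fold, log2 fold change 3.07 ± 0.37, adjusted p = 1.5e-05), higher in 6 of 6 aged animals. Kcnc1, a potassium channel of fast-spiking neurons (ENSMUSG00000058975, chromosome 7, 46396497 to 46438704), stood at 97.3 ± 22.5 against 157 ± 16.6 CPM (-0.69 ± 0.11, adjusted p = 0.00021), and Nrep was again lower at 18 months (-1.10 ± 0.16). Gfap did not differ by more than the spread between animals (0.19 ± 0.13, adjusted p = 0.37).

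The comparison gave 1593 changed genes, 935 up and 658 down (304 and 54 by at least 1 on the log2 scale). The groups did not overlap in 546 of all 14599 genes tested, where chance gives 0.216%, and 499 of these were among the changed genes. The noncoding RNA Gt(ROSA)26Sor, transcribed at the Rosa26 locus (chromosome 6, 113067428 to 113077333), rose most, at 10.2 ± 2.36 against 0.291 ± 0.286 CPM (5.0 ± 0.48), and it was also higher in aged controls (3.46 ± 0.44). Next came Ifi211 (4.53 ± 0.51), Trim30d (3.91 ± 0.50), Ifi204 (3.27 ± 0.32), the class I gene H2-Q7 (3.15 ± 0.40), Trim34a (2.98 ± 0.46), Ifit1 (2.97 ± 0.34), Plac8 (2.88 ± 0.37) and the nucleic acid sensor Zbp1 (2.85 ± 0.40). Lower at 18 months were the steroidogenic enzyme Cyp11a1 (-1.63 ± 0.34), Igsf9 (-1.52 ± 0.33), Slc29a4 (-1.47 ± 0.29) and Pla2g4e (-1.45 ± 0.31). Smaller falls followed in Atp6ap1l (-1.27 ± 0.24), Abi3bp (-1.24 ± 0.25), Lemd1 (-1.10 ± 0.26) and the G-protein regulator Rgs4 (-1.04 ± 0.14). Ttr, the choroid plexus transcript for transthyretin, stood at 14 ± 14.6 against 229 ± 535 CPM, with 1320 CPM in library C of MCAO at 3 months, and its log2 difference of -4.05 ± 1.63 (adjusted p = 0.12) was 0.32 without that library.

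All 32 interferon response genes rose (32 adjusted over the list alone, median 2.00, adjusted p = 0.0022). Of 11 class I genes 9 did (10 over the list alone, median 1.76, adjusted p = 0.0022), with B2m at 1.52 ± 0.15, H2-K1 at 1.88 ± 0.21 and H2-D1 at 1.74 ± 0.16. Chemokine and cytokine genes rose in 12 of 19 cases (15 over the list alone, median 1.07, adjusted p = 0.013). Cxcl10 (2.26 ± 0.35), Cxcl1 (2.01 ± 0.34), Ccl2 (1.45 ± 0.40) and Il33 (1.30 ± 0.14) were among them. Il1b was at 1.07 ± 0.35 (adjusted p = 0.047, lost in 16 of the 24 fits with 1 library left out). Monocyte and macrophage markers rose in 7 of 11 cases (9 over the list alone, median 1.17, adjusted p = 0.037), with Arg1 at 1.46 ± 0.43 (lost in 6 of the 24 fits) and Ccr2 at 0.64 ± 0.41 (adjusted p = 0.33). Without library F of MCAO at 3 months Ccr2 was at 1.49 and past the threshold. Neutrophil markers rose in 2 of 7 (5 over the list alone, median 1.10, adjusted p = 0.047). Endothelial markers rose in 4 of 12 (5 up and 1 down over the list alone, median 0.44, adjusted p = 0.047), among them Cdh5 (1.03 ± 0.20) and Flt1 (0.59 ± 0.13), with Cldn5 at 0.46 ± 0.22 (adjusted p = 0.17, and 0.83 and past the threshold without libraries A and C of MCAO at 3 months). The 4 erythrocyte genes rose in the same comparison (Hba-a1 3.24 ± 0.87, 1.85 without library F of MCAO at 18 months).

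Ion channel genes fell in 7 of 18 cases (13 over the list alone, median -0.35, adjusted p = 0.032), with Scn1a at -0.81 ± 0.15, Kcna1 at -0.57 ± 0.20 (adjusted p = 0.064) and Scn2a at -0.34 ± 0.15 (adjusted p = 0.14). Presynaptic genes fell in 10 of 19 cases (12 over the list alone, median -0.32, adjusted p = 0.037) and neuronal markers in 8 of 18 (1 up and 8 down over the list alone, median -0.25, adjusted p = 0.037). Rorb was at -0.76 ± 0.14 and Rbfox3 at -0.60 ± 0.12, Snap25 at -0.12 ± 0.18 and Syt1 at -0.07 ± 0.17. Markers of neighbouring regions moved in the same comparison without a call as a list with an estimated correlation. The striatum list had a median of -0.62 (2 of 9 down, adjusted p = 0.345, scores of 4.27 ± 0.66 against 4.90 ± 0.80), and the list of hippocampus and thalamus 0.39 (3 up and 1 down of 8, adjusted p = 0.14, 4.49 ± 0.08 against 4.22 ± 0.11). Without libraries A and C of MCAO at 3 months, Snap25 was at -0.43 and past the threshold, and Syt1 at -0.27 and not past it. Without library C of MCAO at 18 months the comparison gave 951 genes, without library E 1038, and with spike-in scaling 671, where the medians of the lists of ion channels, presynaptic vesicle machinery and neurons were -0.15, -0.093 and -0.060. The 12 MCAO libraries fitted alone gave 607 genes, and 46 when the neuron marker score was a covariate in them.

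**Figure D3:**
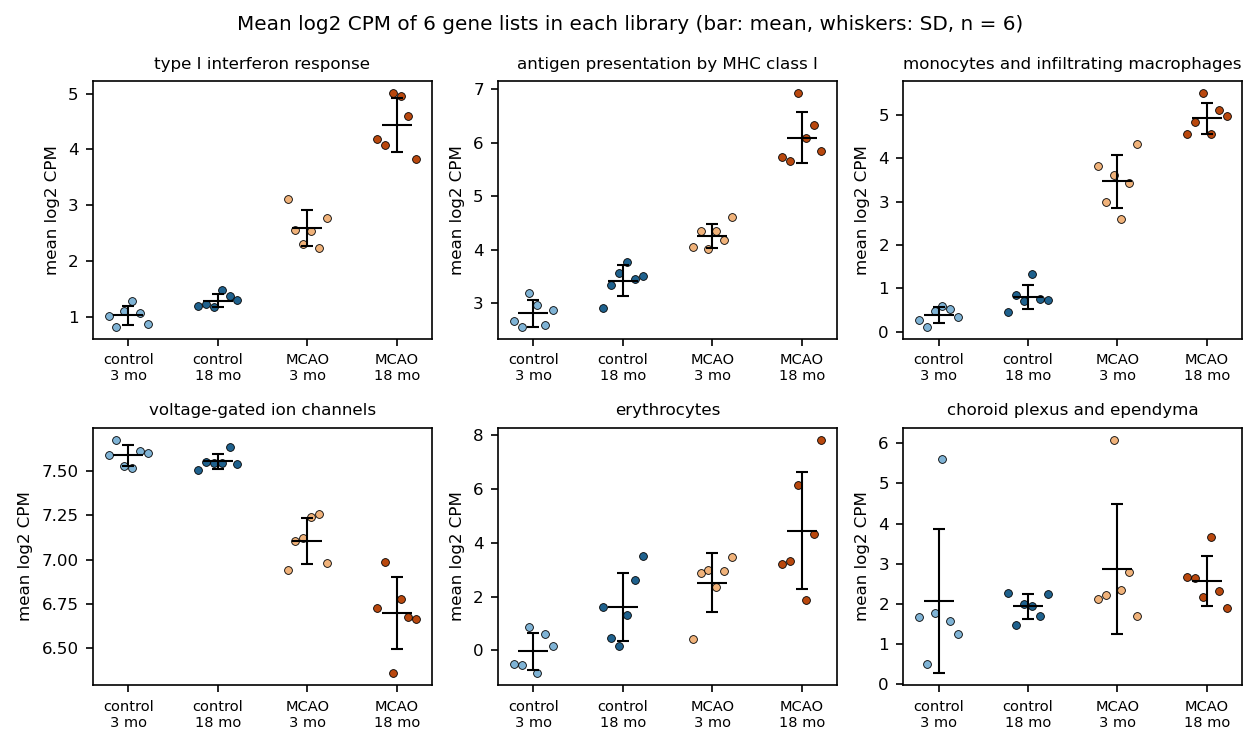
Mean log2 CPM of 6 gene lists (vertical axes) in each library (points) by group (horizontal axis), with mean (bar) and SD (whiskers), n = 6. The interferon score was 4.44 ± 0.49 after MCAO at 18 months and 2.59 ± 0.32 at 3 months without overlap, and erythrocyte and choroid plexus scores show single libraries far from their groups.

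The direct test of whether MCAO acted differently at the 2 ages called 12 genes, 6 in each direction. Gfap had the smallest p: its MCAO effect was smaller at 18 months by 1.89 ± 0.20 on the log2 scale (adjusted p = 1e-05). The levels reached after MCAO were 249 ± 35.2 CPM at 3 months and 285 ± 37.4 CPM at 18 months from unequal controls. The interferon-induced genes Isg15 (3.30 ± 0.57, adjusted p = 0.027), Ifi44 (3.01 ± 0.60, adjusted p = 0.045), Rsad2, encoding viperin (2.55 ± 0.41, adjusted p = 0.011), and Helz2 (2.44 ± 0.49, adjusted p = 0.047) rose more at 18 months. Ccl3 rose less (-3.89 ± 0.69, adjusted p = 0.027), at 0.0307 ± 0.0753 and 5.49 ± 1.5 CPM in control and MCAO cortex at 3 months and 0.994 ± 0.460 and 6.77 ± 1.05 CPM at 18 months, so that the value rests on 1 count in young controls.

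The potassium channel Kcnc1 (-0.82 ± 0.16, adjusted p = 0.036) had a more negative MCAO effect at 18 months, as did Klhl40 (-1.42 ± 0.29), while the endothelial and podocyte sialomucin Podxl had a more positive one (1.00 ± 0.19, adjusted p = 0.038). Kcnc1 stood at 206 ± 15.7 and 157 ± 16.6 CPM in control and MCAO cortex at 3 months and at 226 ± 11.2 and 97.3 ± 22.5 CPM at 18 months. The pseudogene Gm8292 (1.20 ± 0.23) and the unclassified transcript Gm43398 (-1.47 ± 0.30), also called, were chosen after their values were seen. As lists, interferon response genes differed (3 up over all genes, 21 over the list alone, median 1.59, adjusted p = 0.044). Endothelial markers did too (3 over the list alone, median 0.55, adjusted p = 0.020), with Cldn5 at 0.55 ± 0.33 and Flt1 at 0.71 ± 0.19. Class I genes (8 over the list alone, median 1.04) and ion channels (7 down over the list alone, median -0.38) both had adjusted p = 0.052 with an estimated correlation. Ifit1 (2.35 ± 0.65, adjusted p = 0.13), Ifit3 (1.64 ± 0.38, adjusted p = 0.083), B2m (1.01 ± 0.21, adjusted p = 0.057) and C4b (-1.72 ± 0.35, adjusted p = 0.051) did not pass alone. Gfap passed the threshold in every alternative tried, while Rsad2 lost its call in 4 of them and Klhl40 in 26. Of the 24 fits with 1 library left out, the call was lost in 1 for Rsad2, 3 for Ccl3, 8 for Isg15, 12 for Kcnc1, 13 for Podxl, 15 for Helz2, 16 for Ifi44 and 17 for Klhl40. DESeq2 called 118 genes and voom 218, and with 1 library left out edgeR called 1 (without library D of the young controls) to 68 (without library F of MCAO at 3 months).

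Across the MCAO libraries, the scores of type I interferon response and of monocytes and infiltrating macrophages of the 2 ages did not overlap (2.24 to 3.12 against 3.82 to 5.01, and 2.60 to 4.33 against 4.56 to 5.50), so no correlation over all 12 is given for them, since the ages form separate clusters. Their correlation with the neuron score is given within each age, and over the 12 libraries as deviations from the age means. For interferon, Pearson's r was -0.49 at 3 months (exact permutation p = 0.325, adjusted 0.488 over 3 relations) and -0.55 at 18 months (exact permutation p = 0.25, adjusted 0.75), with Spearman's rho of -0.43 and -0.60. For monocytes r was -0.52 (exact permutation p = 0.292, adjusted 0.488) and -0.21 (exact permutation p = 0.69, adjusted 0.985), with rho of -0.66 and -0.26. As deviations from the age means, r was -0.53 for interferon (permutation p = 0.081, adjusted 0.243) and -0.37 for monocytes (permutation p = 0.239, adjusted 0.358). Reactive astrocyte and neuron scores over the 12 libraries had r = -0.55 (permutation p = 0.0666) and rho = -0.60 (permutation p = 0.0425), and r = -0.56 (permutation p = 0.0957) and rho = -0.62 (permutation p = 0.0587) without the 2 libraries farthest from the median neuron score. Over the 12, rho was -0.48 (permutation p = 0.121) with scaling by library totals and -0.55 (permutation p = 0.0664) with a prior count of 0.5. As deviations from the age means, r was 0.06 (permutation p = 0.861). Within the ages r was 0.12 and -0.01. None of the relations given here passed the threshold by Pearson's r.

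Some of the named genes have near-identical relatives whose reads the counting could divide or discard, so that their values are uncertain: the H2 genes, Ifit3, Hba-a1 and Hbb-bs, Trim30d, Ifi204 and Ifi211, C4b and the Cd300 family. Gt(ROSA)26Sor is annotated as antisense to another gene, and whether strand was used in counting is not given in the sources used here.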

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

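The tests of patterns in this part were chosen after the results were seen, apart from the difference of the MCAO effect between the ages and the regroupings of libraries for the genes changed at both ages, which were planned before their results were seen. The fit with the neuron score as a covariate was also planned, but the bounds set on its list medians were chosen afterwards.

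Genes and lists whose MCAO effect differed between 18 and 3 months were picked out by the interaction test. On the log2 scale the differences were 3.30 for Isg15, 3.01 for Ifi44, 2.55 for Rsad2, 2.44 for Helz2, 1.20 for Gm8292 and 1.00 for Podxl, and -0.82 for Kcnc1, -1.42 for Klhl40, -1.47 for Gm43398, -1.89 for Gfap and -3.89 for Ccl3. With a preset correlation between genes, list medians differed by 1.59 for the interferon response, 1.04 for MHC class I, 0.55 for endothelial cells, 0.35 for the cell cycle, 0.32 for oligodendrocytes, 0.29 for oligodendrocyte precursors and 0.17 for ribosomal proteins. In the other direction they differed by -0.12 for neurons, -0.21 for axon and node of Ranvier, -0.25 for presynaptic genes, -0.38 for ion channels and -0.72 for striatal markers. With an estimated correlation only the interferon and endothelial lists were called.

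Interferon response genes were higher at 18 than at 3 months after MCAO, with a median log2 change of 2.00. Fewer neurons, or more lesion in the dissected tissue, would lower that median toward 0 once the neuron score is a covariate. It stayed at 1.51 (SD over genes 0.699, against 0.719 before), with a positive change in all 32 genes, although only 7 were past the threshold. This argues against the neuron share, as far as this score measures it, as the whole cause. The genes share the same libraries, so their common sign is not independent support. The neuron score was also lower at 18 months (8.32 ± 0.16 against 8.58 ± 0.14), so the covariate may not remove the whole of a neuron share. Aged controls had a lower neuron score than young ones too (9.07 ± 0.05 against 9.20 ± 0.06). That fit holds the 12 MCAO libraries alone, which lowers the number of calls by itself, and why the calls ended was not tested, so that a part stays open. Without libraries A and C of MCAO at 3 months the median was 2.02 with 31 genes called, and without libraries C, E and F of MCAO at 18 months, rich in haemoglobin transcripts, it was 2.025 with 24 called, which argues against both sets as the cause. Age itself stays open and was not tested apart from these.

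Ion channel genes were lower at 18 than at 3 months after MCAO, with a median log2 change of -0.35. Without libraries A and C of MCAO at 3 months it was -0.43 with 10 genes called, which argues against those libraries as the cause. Foreign RNA would have to make up 21.5% of a library to lower the list by its median. Erythrocyte genes, the abundant transcripts of blood, held 0.136% of counts at most in libraries C, E and F of MCAO at 18 months. This argues against dilution by blood as the whole cause, as far as these genes measure it. Reads of haemoglobin genes may be divided or discarded in counting. Without libraries C, E and F the median was -0.245 with 2 genes called, so a contribution of these libraries stays open. With the neuron score as a covariate in the 12 MCAO libraries alone it was -0.19 with no call left by edgeR, a value between the bounds set for that explanation, and with spike-in scaling -0.15, again with no call. A smaller neuron share therefore stays open beside age, and cannot be told apart from it in 12 libraries, because the neuron score was also lower at 18 months (8.32 ± 0.16 against 8.58 ± 0.14). In controls the neuron score was lower at 18 months as well (9.07 ± 0.05 against 9.20 ± 0.06). A difference in the dissected region was not tested.

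Libraries A and C of MCAO at 3 months stood apart from the other 4. Across 10389 genes their difference from the others rose with the GC content of the last bases of the transcript (Spearman's rho 0.497), and the 183 genes lower by at least 2 on the log2 scale had a median GC content of 32.5% against 40% for all. Poor recovery of AU-rich transcript ends fits these values and is a candidate cause. The other 14 ways to take 2 of the 6 libraries reach 0.470 in absolute size, but that value is negative and has A and C among the other 4, so it measures much of the same difference again. As a cause shared by A and C, low depth is argued against by 13.1 M counts in A, where the others had at most 5.24 M. Choroid plexus tissue as a shared cause is argued against by the score of A, 2.11, under the 2.78 reached among the other 4. For C alone neither is argued against, since it had the lowest total of the 6, 4.17 M, and the highest choroid plexus score, 6.09. No biological explanation was tested.

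Chance flags about 1 in 20 groups of 6 libraries as holding a library far from the others, and here 23 of 240 were. Among library measures these were the 13.1 M counts of A of MCAO at 3 months (others 4.17 to 5.24 M) and 0.570% ambiguous reads in A of the aged controls (others 0.485% to 0.511%). List scores far from the rest in the aged controls were microglia 3.94 in F, B cells 3.26 in F, mitochondrially encoded genes 2.84 and oxidative phosphorylation 7.85 in A, and ion channels 7.64 in E. In the young controls they were oligodendrocyte precursors 4.37 and cell death 1.77 in A, MHC class II 0.602 in B and choroid plexus 5.62 in D. After MCAO at 3 months they were erythrocytes 0.433 in A, choroid plexus 6.09 in C, and reactive astrocytes 4.74 and presynaptic genes 8.215 in F, and at 18 months B cells 7.125 in C.

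Single genes stood out in the same way: Cd5l at 279 CPM in A and Ttr at 1320 CPM in C of MCAO at 3 months, Hba-a1 at 137 CPM in F and Ttr at 42.2 CPM in D of MCAO at 18 months, Cst7 at 17.0 CPM in D and Xist at 1391 CPM in A of the aged controls, and Ccl3 at 0.184 CPM (1 count) in A of the young controls, where the others had none. Spike-in RNA, which entered no gene test apart from the fits with spike-in scaling, took a mean of 9.10% of counts after MCAO at 3 months and 8.14% at 18 months, above the controls. In libraries A to C it was 9.53 ± 0.88% against 7.36 ± 0.84% at 3 months and in D to F 8.68 ± 1.17% against 5.37 ± 0.12%, so the level of controls also differed between these 2 sets of letters.

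Regrouping the libraries at random, 100 times for each comparison with the real grouping included, tested whether chance could give as many calls. For genes, 1 of 100 groupings (the real one) was as large in each comparison: 5451 against 2565 at most for the others in MCAO at 3 months, 6606 against 3479 at 18 months, 88 against 1 for age in controls, 1593 against 732 for age after MCAO and 12 against 6 for the interaction. This argues against chance in the comparisons of 2 groups. For the interaction it cannot decide, since regrouping by age within each condition also mixes the effect of age itself into the spread between libraries. In the MCAO comparisons the highest other counts came from groupings that moved 1 library of each group, and are thus close to the real one. For genes changed at both ages, 4334 stood against 0. Those regroupings exchanged MCAO and control labels within each age, which takes away the MCAO effect itself. They therefore cannot decide whether the response is shared between the ages. Lists with an estimated correlation reached 19 against 1, 26 against 0, 4 against 3, 10 against 13 (2 of 100 groupings as large) and 2 against 1. This argues against chance in the comparisons of 2 groups, though by 1 list only for age in controls. In age after MCAO the grouping with 13 lists had 1 library of MCAO at 18 months in place, and is thus close to the real one with its labels exchanged. For the interaction the count cannot decide, for the reason given for genes. With the preset correlation, 26 against 29 (6 of 100 as large) and 12 against 28 (40 of 100) leave chance open for age after MCAO and the interaction. For age in controls, 18 against 15 (1 of 100) argues against it. For MCAO, 31 against 32 (6 of 100) at 3 months and 32 against 33 (4 of 100) at 18 months cannot decide. There the other groupings as large had 1, 2 or 5 libraries of the MCAO group in place, and so keep part of the real difference.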

How the results depend on the processing

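Chosen after the data were seen were letters A to C and D to F, alone or as a block, the GC correction, spike-in scaling and the fits without sets of libraries; the other alternatives were planned. Of 227 gene results, 184 of them calls, 108 kept their side of the threshold in every alternative. Over 9771 repeats 9154 did, 503 lost a call, 114 gained one and 0 changed direction while called. The largest losses were with letters A to C alone (70 of 227), D to F alone (50) and the neuron covariate (34 of 78).

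For MCAO against control at 3 and 18 months, letters A to C alone gave 2990 and 3594 genes, with 3 libraries per group, and 2077 for genes changed by MCAO the same way at both ages. For age in controls, DESeq2 gave 174 genes, voom 426, the 12 control libraries alone 226, letters A to C 3, D to F 15, the fit without libraries A and C of MCAO at 3 months 185 and spike-in scaling 39. For age after MCAO, the 12 MCAO libraries alone gave 607, the neuron covariate in these 12 libraries 46, letters A to C 113, the fit without libraries C, E and F of MCAO at 18 months 311 and spike-in scaling 671. For the interaction, DESeq2 gave 118, voom 218, letters A to C 1, D to F 1, the block of A to C against D to F 31, and the fits without libraries A and C of MCAO at 3 months 135, without the choroid-rich libraries 1 and without libraries C, E and F of MCAO at 18 months 3, and spike-in scaling gave 3. Lists called fell from 31 to 19, 18 to 4, 26 to 10 and 12 to 2 with an estimated correlation in MCAO at 3 months, age in controls, age after MCAO and the interaction. Apart from the smaller number of libraries, the cause was not tested.

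Leaving out 1 library at a time gave 4891 to 5758 genes for MCAO at 3 months, 6084 to 7222 at 18 months, 4080 to 4424 at both ages, 51 (without D of the aged controls) to 137 (without A of MCAO at 3 months) for age in controls and 951 (without C of MCAO at 18 months, and 1038 without E) to 1811 for age after MCAO. For the interaction it gave 3, 6, 2, 1 and 2 without A, B, C, D and F of the young controls, 20, 3 and 3 without A, B and C of the aged controls, 33, 4, 4 and 68 without A, C, E and F of MCAO at 3 months, and 23, 46, 5, 3 and 19 without A, B, C, E and F of MCAO at 18 months. With the letters as a replicate block the 5 counts were 5554, 6671, 98, 1743 and 16, but libraries of the same letter correlated with a median r of only 0.028 and 4 of 24 libraries matched their own letter best, so no pairing by letter was seen. The GC correction gave 5574, 6787, 107, 1683 and 16 genes.

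The direction of the counts depends on scaling, the test and the libraries. For age in controls voom gave 191 genes up and 235 down. For the interaction, thinned counts gave 12 up and 3 down, with 7 genes shared, and the fit without libraries A and C of MCAO at 3 months 91 up and 44 down. Letters A to C gave 1967 up and 1023 down for MCAO at 3 months, 2246 up and 1348 down at 18 months and 85 up and 28 down for age after MCAO, where the fit without C, E and F of MCAO at 18 months gave 227 up and 84 down and the neuron covariate 40 up and 6 down. Library totals moved the median of all genes by 0.133 and 0.116 on the log2 scale for MCAO at 3 and 18 months, with 3729 genes up and 1203 down, and 4143 up and 2134 down, and gave 4 up and 7 down for the interaction. Upper-quartile scaling gave 778 up and 936 down for age after MCAO and 6 up and 10 down for the interaction. Spike-in scaling moved the median by -0.455, -0.289, 0.0446, 0.208 and 0.164 in the 5 comparisons, with 1411 up and 6178 down for MCAO at 3 months, 2007 up and 4119 down at 18 months, 33 up and 6 down for age in controls and 646 up and 25 down for age after MCAO. Thinned to 3.30 M counts per library, the comparisons gave 4823, 5934, 76, 1273 and 15 genes.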

Other observations

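The gene lists here were planned, and the comparison of age effects between control and MCAO cortex was chosen after the results were seen. Further groups moved with MCAO. All 7 MHC class II genes rose at 18 months (median log2 change 3.47, adjusted p = 0.046), as did 7 of 10 markers of fibroblasts and meninges (median 3.56, adjusted p = 0.12 with an estimated correlation) and 8 of 10 pericyte markers (median 0.85, adjusted p = 0.11 with an estimated correlation). Lipid storage and efflux genes rose in 9 of 13 cases at 3 months (10 adjusted over the list alone, median 1.45, adjusted p = 0.0091) and in 11 at 18 months (median 1.66, adjusted p = 0.0069), and in 7 of them with age after MCAO (8 over the list alone, median 0.47, adjusted p = 0.043). All 11 senescence reporters (medians 3.17 and 3.21, adjusted p = 0.008 and 0.0093), 12 and 11 of 14 cell death genes (medians 1.98 and 2.21, adjusted p = 0.0034 and 0.0042), and 9 and 10 of 15 antioxidant genes (medians 0.72 and 0.78, adjusted p = 0.008 and 0.012) rose. Oligodendrocyte precursor markers rose in 8 and 9 of 10 cases (medians 0.76 and 0.99, adjusted p = 0.04 and 0.014), and ribosomal protein genes in 13 and 16 of 20 (medians 0.55 and 0.74, adjusted p = 0.073 and 0.046 with an estimated correlation).

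Myelin genes rose with MCAO in 5 of 12 cases at 3 months (median 0.14, and -0.30 with spike-in scaling) and in 9 at 18 months (median 0.51), and with age after MCAO in 6 (9 over the list alone, median 0.50), with adjusted p = 0.061 with an estimated correlation in the last. Mbp was at 0.87 ± 0.15 and Ermn at 1.13 ± 0.15 there, and Mog at 0.33 did not pass (adjusted p = 0.33). Genes of axons and the node of Ranvier fell with MCAO in 9 of 17 cases at 3 months (median -0.36, adjusted p = 0.094 with an estimated correlation) and in 13 at 18 months (median -0.64, adjusted p = 0.024). Hypoxia and glycolysis genes rose in 7 and fell in 1 of 17 cases at 18 months (median 0.29, adjusted p = 0.034). With spike-in scaling that median was only 0.0026, so the rise of this list depends on the scaling. At 3 months 5 were up and 2 down (median 0.10, and a median of -0.37 with spike-in scaling). Among the lists without a call in either MCAO comparison with an estimated correlation were oxidative phosphorylation, where 6 and 14 of 25 genes fell (medians -0.22 and -0.31), cholesterol synthesis (7 and 6 of 16 down, medians -0.31 and -0.26) and immediate early genes (5 of 15 down at each age, medians -0.75 and -0.46).

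Of the 88 genes that differed with age in controls, 59 also differed with age after MCAO in the same direction, 41 up and 18 down, where independent lists would share 3.27 and 1.67. The log2 changes of the 2 comparisons, which have no library in common, correlated with r = 0.39 over all genes. Gt(ROSA)26Sor (3.46 in controls and 5.0 after MCAO), Clec7a (4.58 and 2.55), Cdkn2a (3.57 and 1.60), C4b (3.04 and 1.32), Hapln2 (1.67 and 1.21) and Il33 (0.94 and 1.30) were higher in aged cortex of both kinds. Nrep (-1.42 and -1.10), Abi3bp (-1.67 and -1.24), Met (-2.14 and -0.99) and Rgs4 (-0.63 and -1.04) were lower. The other 29 genes passed the threshold in controls alone, and for 3 of them the effect itself differed between control and MCAO cortex.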
